A study of Mus musculus with 28 samples.

How the data were processed

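Whole-brain RNA from 28 mouse samples was measured by QuantSeq, a 3′ tag protocol in which each transcript gives a read near its polyadenylated end, so that counts need no correction for transcript length. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were prepared with the forward (FWD) kit. The model is cuprizone, a copper chelator given in food that kills oligodendrocytes and strips myelin, which grows back once it is withdrawn. The labels give 4 groups of 7 samples each: naive mice, mice at the peak of demyelination and mice in remyelination, all carrying a floxed TNFR1 gene, and mice in remyelination that also carried a tamoxifen-inducible Cre recombinase in the Cx3cr1 locus and had lost TNFR1 from microglia after tamoxifen. The design text codes these stages by the number 5 for the peak of demyelination and 6+1 for remyelination, without stating a unit. It speaks of 7 samples per group and not of separate animals, so every p-value of a gene here measures the spread between these samples. The p-values of gene lists, described below, also rest on a correlation assumed or estimated between genes.

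Each deposited table holds RSEM gene results of a single library, and the expected counts in it, which are estimates of reads per gene and need not be whole, are the values the authors deposited, per the file headers. They are not normalised. The submitters' processing notes name FastQC, cutadapt, STAR, RSEM and edgeR with the mouse build GRCm39. The roles, settings and versions of these tools, the annotation release and the strand setting are not given in the sources used here. The TPM and FPKM columns of the same tables were not used. Between 96.59 and 97.69% of the expected counts per library were whole numbers within 0.005, and all were rounded to whole numbers before testing. The tables list 55414 genes by versioned Ensembl identifiers without symbols. Symbols were taken from a GENCODE M21 annotation on GRCm38 by identifier, which matched 52081 genes. Genes without a match held 10.76% of all counts and 16 of them were tested. No coordinates are given, because that annotation is of another build than the authors' tables. Where genes overlap on opposite strands, or have near-identical copies such as Hba-a1 and Hba-a2, RSEM may divide reads between them, and their values are uncertain.

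Library totals ranged from 1522913 to 2150500 counts in naive, 1695221 to 2417151 in demyelination, 1864535 to 3137254 in remyelination and 1531719 to 2986498 in knockout libraries. In these, 3 counts, taken here as the floor of detection, correspond to between 0.956 and 1.97 CPM, the usual unit of counts scaled to library size. Intervals and floors cover counting error only. Replicate libraries were compared by a chi-square test of their counts, and the smallest value per degree of freedom was 2.53, so no library was counted as a duplicate. All 28 libraries held counts of Y-linked genes and at most 7 counts of Xist, so a sex term could not be fitted.

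Counts were normalised by TMM and filtered by filterByExpr, which left 12423 genes. They were tested with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) in a single fit of all 28 libraries with a mean for each of the 4 groups. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed below an adjusted p of 0.05. The common biological coefficient of variation was 19.5%. Group values are mean CPM ± SD over 7 libraries, and fold changes are on the log2 scale with their standard error (SE).

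Gene lists were fixed before the data were examined, as were the comparisons, the tests, the naming rule and all alternatives not named as added. There were 19 biology lists: myelin and mature oligodendrocyte, newly formed oligodendrocyte, oligodendrocyte precursor, homeostatic microglia, disease-associated microglia, complement with Fc receptor and lysosome, cholesterol synthesis, cholesterol efflux and lipid storage, reactive astrocyte, type I interferon response, TNF and NF-kB targets, antigen presentation, classical (M1) and alternative (M2) activation, integrated stress response, cell cycle, neuron, immediate early and oxidative phosphorylation. There were 16 check lists for other cells, dissection, time of day, stress, sex and RNA quality: lymphocytes, monocytes with neutrophils and border macrophages, endothelial and mural cells, choroid plexus, ependyma, meninges, red blood cells, pituitary, cerebellum, striatum, hypothalamus, olfactory bulb, circadian clock, glucocorticoid response, sex and mitochondrial transcripts. Each list was tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with adjustment over the lists of its kind and all 4 comparisons. It was run again with the correlation estimated from the data. Members that passed were counted over all genes tested and again adjusted over the list alone. Lists with fewer than 3 measured members had no camera test. Some genes belong to more than 1 list, among them C4b, Apoe, H2-D1 and Mrc1.

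Named genes followed a rule: in each comparison the 8 largest rises and the 8 largest falls among called genes with a mean of at least 2 CPM and every library of one group on one side of the other group's mean, leaving out unnamed genes and pseudogenes, the 3 members of each biology list and the 1 member of each check list with the smallest p, and the targeted gene with Tnf, Tnfrsf1b and Cx3cr1 in the knockout comparison. Genes outside the rule are marked as named after their values were seen; they were not refitted under the alternatives. Some results that the rule names are not reported here.

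A demyelination score was computed per library as the mean log2 CPM of genes raised minus that of genes lowered between naive and demyelination libraries, with the genes chosen from those 14 libraries alone. Knockout and control scores were compared by a two-sided exact permutation test over all 3432 splits. The reversal of the demyelination response was measured by overlap of calls, beside the overlap of independent lists and fits with the shared libraries divided, and by the covariance of fold changes, beside 10 simulations of unchanged groups. The overlap in those simulations is not reported, because they called 0.1 genes on average and could share almost none. A fold against a group with no counts was computed as a bound against 3 counts over that group, and ratios with few counts carry a 95% interval.

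The gene test was tried on simulated counts in which a seeded set of genes was changed by known folds. Of the genes changed by 2-fold it recovered 76.1% in the demyelination against naive simulation, 76.1% in remyelination against naive, 71.6% in remyelination against demyelination and 86.6% in knockout against control, among 12216, 12202, 12216 and 12215 genes tested. Of the genes changed by 1.5-fold it recovered 34.3, 38.8, 43.3 and 37.3%. Each comparison had a single simulation, with 67 genes at each of these 2 folds and genes drawn independently, so differences between comparisons are not read. The knockout simulation called 171 genes, where the data called 6. With fewer changed genes the adjusted p is harder to pass, so recovery in the data can be lower than simulated. Alternatives covered a stricter adjusted p, a minimum fold change (glmTreat), DESeq2 1.42.0 and its size factors, library totals in place of TMM, other low-count filters, unrounded counts, the replicate number as a block, the mitochondrial share as a covariate, fits of only the groups compared, and each library left out in turn. Alternatives added after seeing the data were a robust estimate of the spread, the omission of naive library 1 and knockout library 1, comparisons of the knockout group with the naive and demyelination groups, and counts of list members at an unadjusted p and by DESeq2.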

Results

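The series holds 28 whole-brain 3′ mRNA libraries from mice, 7 in each of 4 groups: naive, peak demyelination under cuprizone, remyelination, and remyelination after deletion of TNFR1 in microglia (the knockout group). The other 3 groups carried the floxed TNFR1 gene without the deletion, and the remyelination group among them is the control of the knockout group. The comparisons follow the stages of demyelination and remyelination, and then ask what the microglial deletion changed in remyelination. The most abundant gene, ENSMUSG00000119584.1, for which no symbol was found, took between 1.33 and 25.54% of a library's counts. The extremes were knockout library 1 and naive library 1, which stood apart from their groups and are left out together in an added alternative. All adjusted p-values of genes are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 12423 genes, and those of lists from camera.

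The targeted gene, Tnfrsf1a (ENSMUSG00000030341.18), which encodes TNFR1, was measured in every library. The 7 knockout libraries held 20.5, 21.9, 20.4, 16.5, 23.2, 21.8 and 30.4 CPM, a mean of 22.1 ± 4.22 (SD, n = 7), and the remyelination control libraries 23.2 ± 4.47 (n = 7). The log2 fold change was −0.05 (SE 0.167, adjusted p = 0.961). A 3′ tag can lie outside the deleted part of a gene and cells other than microglia also express Tnfrsf1a, so this level checks nothing about the deletion. Across the stages the same gene, followed here because it is the target, was 13.4 ± 3.07 CPM in naive and 27.3 ± 4.89 CPM in demyelination brains. That is a rise of 1.01 on the log2 scale (SE 0.176, adjusted p = 0.000205). In remyelination it was still 0.77 higher than in naive brains (adjusted p = 0.0214). Tnf, its ligand, had 1 count in the remyelination group and 0 in the other 3, and Tnfrsf1b, the second TNF receptor, had between 8 and 28 counts per group. Neither reached the level needed for a test.

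At the peak of demyelination, transcripts of myelin and mature oligodendrocytes fell and those of activated microglia rose, both against naive brain. Mal (ENSMUSG00000027375.15), a proteolipid of compact myelin, fell by 2.01 on the log2 scale (SE 0.114, adjusted p = 1.78e-16), from 273 ± 34.8 to 68.0 ± 16.4 CPM (n = 7 per group). Lyz2 (ENSMUSG00000069516.9), a lysozyme of myeloid cells, rose by 2.92 (SE 0.202, adjusted p = 7.67e-14), from 11.5 ± 5.55 to 89.4 ± 17 CPM. Clec7a (ENSMUSG00000079293.12), a pattern recognition receptor, had 106 counts in demyelination and 0 in naive libraries, so it was at least 33.5-fold higher against a floor of 3 counts over the group. Of the 12423 genes tested, 249 changed, 162 upward and 87 downward, and 112 of them by more than 2-fold.

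Of the 33 measured genes of the myelin and mature oligodendrocyte list, 20 fell and 1 rose (28 and 1 adjusted over the list alone), with a median of −0.94 (camera adjusted p = 2.42e-63). Mobp, a myelin structural gene, fell by 1.29 (SE 0.107), from 374 ± 32.5 to 153 ± 32.3 CPM. The falls were deeper in Ppp1r14a at −1.80, Opalin, a membrane protein of oligodendrocytes, at −1.79, and Anln at −1.79. The member that rose was Trf, which encodes transferrin (+0.49, named after its value was seen). Outside the lists Adamtsl4 fell by 1.74 and Tmem125 by 1.62. No member passed among the 12 newly formed oligodendrocyte genes (6 had an unadjusted p under 0.05, DESeq2 called 0, camera adjusted p = 0.652). Their median was −0.03 and their mean +0.10. None passed among the 15 oligodendrocyte precursor genes either (3 at an unadjusted p under 0.05, DESeq2 called 0, camera adjusted p = 0.9). In the newly formed list Bcas1 and Itpr2, which mark differentiating oligodendrocytes, had log2 fold changes of +0.39 and +0.41 (adjusted p = 0.183 and 0.178). Here 2 members rose and 1 fell adjusted over the list alone.

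Of the 23 disease-associated microglia genes measured, 18 rose (20 adjusted over the list alone, camera adjusted p = 7.55e-82). Their median was +1.29, which stays as it is with Clec7a at its bound. Beside Lyz2 they included Lgals3, which encodes galectin-3, at +3.83 (SE 0.401), the chemokine Ccl6 at +3.58 (SE 0.372), the oxidase subunit Cybb at +3.09 (SE 0.421), and the lysosomal protease Ctsd at +1.55 (SE 0.125). Cst7 (ENSMUSG00000068129.6), a cystatin, had 186 counts against 1, a ratio of 176 with a counting interval of 31.2 to 6990. Itgax (ENSMUSG00000030789.10), which encodes CD11c, had 178 against 3, a ratio of 56.2 with an interval of 18.9 to 275. Among the 21 genes of complement, Fc receptors and lysosome, 14 rose (18 adjusted over the list alone, median +1.52, camera adjusted p = 5.41e-51). These had Ctss at +1.69, the complement component C4b at +2.12 and the phagocyte marker Cd68 at +2.67. Of 16 homeostatic microglia genes, 4 rose (4 adjusted over the list alone, camera adjusted p = 1.2e-07). Among them were Fcrls at +1.76, Csf1r, the receptor on which microglia depend, at +0.84, and Cx3cr1 at +0.67 (adjusted p = 0.0437, named after its value was seen). Outside the lists the leukocyte surface genes Cd52 and Cd300c2 rose by 3.58 and 3.24.

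Astrocyte, interferon and antigen presentation genes rose as well. In the reactive astrocyte list 7 of 15 rose (10 adjusted over the list alone, camera adjusted p = 1.53e-25). They included Serpina3n at +2.92 (SE 0.302) and the intermediate filament gene Vim at +1.35, from 101 ± 17.8 to 259 ± 26.7 CPM. In the type I interferon list 4 of 12 rose (7 adjusted over the list alone, camera adjusted p = 1.51e-11). They were Lgals3bp at +1.81, Ifit3 at +1.82, Irf9 at +1.09 and Trim30a at +1.10, the last named after its value was seen. In the antigen presentation list 3 of 7 rose (4 adjusted over the list alone, camera adjusted p = 6.85e-10). They were B2m at +1.09, H2-D1 at +0.86 and H2-K1 at +0.83, all of class I.

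Cholesterol synthesis fell and its efflux partners rose. Of 24 synthesis genes, 8 fell (11 adjusted over the list alone, median −0.35, camera adjusted p = 1.1e-13). Among them were Hmgcs1, the enzyme before the rate-limiting step, at −1.09 (256 ± 38.9 to 120 ± 15.6 CPM), Msmo1 at −0.78 and Sc5d at −0.63. Of 12 genes of efflux and lipid storage, 3 rose, as they did adjusted over the list alone (camera adjusted p = 1.61e-08). They were Apoe at +1.04, the exporter Abca1 at +1.01 and Apoc1 at +2.64. In the integrated stress response list 4 of 20 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 6.19e-05). Nupr1 rose by 2.43, from 2.86 ± 1.64 to 15.1 ± 3.55 CPM, and Ddit3, which encodes CHOP, by 0.79. Eif4ebp1 and Slc7a11 rose by 1.41 and 0.61 (both named after their values were seen), and Ddit4 fell by 0.57. The 30 oxidative phosphorylation genes had a median of +0.14 (camera adjusted p = 0.000707, but adjusted p = 0.179 with an estimated correlation). None passed (5 at an unadjusted p under 0.05, DESeq2 called 0).

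Among the lists for other cells, dissection, stress and RNA quality, the glucocorticoid response list was higher, with 4 of 7 members raised (5 adjusted over the list alone, median +0.57, camera adjusted p = 1.17e-07). Whether glucocorticoids raised these members was not tested. Mt2, a metallothionein gene, rose by 1.04, from 307 ± 46.4 to 631 ± 134 CPM, and Zbtb16, Cdkn1a and Mt1 by 1.05, 0.77 and 0.57 (these 3 named after their values were seen). No member passed among cerebellum (11 genes, 2 at an unadjusted p under 0.05, camera adjusted p = 0.126), meninges (8, 3, 0.263), striatum (7, 1, 0.136), hypothalamus (4, 0, 0.732), olfactory bulb (5, 0, 0.814), red blood cell (4, 0, 0.962), sex (4, 1, 0.354) and mitochondrial genes (13, 0, 0.687). None passed either among endothelial and mural (14, 3, 0.958, median −0.17, mean 0.00, test downward), clock (12, 3, 0.0943) and choroid plexus genes (7, 2, 0.687), the 2 lymphocyte genes (0), the 2 ependymal genes (0) or the 1 monocyte and border macrophage gene (1). Adjusted over the list alone, 3 clock genes and 1 choroid plexus gene rose, while 1 choroid plexus gene and the border macrophage gene fell. DESeq2 called 1 clock and 1 choroid plexus gene and 0 in the others of these lists, and of the pituitary list 0 genes were measured.

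No member passed in the neuron list (22 genes, 4 at an unadjusted p under 0.05, camera adjusted p = 0.365), the immediate early list (13 genes, 0, 0.615), the TNF and NF-kB target list (9 genes, 1, 0.819) or the cell cycle list (7 genes, 0, 0.782). The TNF list had a median of −0.01 but a mean of +0.09. None passed in the M2 list (3 genes, 2 at an unadjusted p under 0.05, 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.654) or among the 2 measured M1 genes (1 at an unadjusted p under 0.05). DESeq2 called 0 members of these 6 lists. The list calls with a camera adjusted p under 0.05 in this comparison all held with an estimated correlation, apart from oxidative phosphorylation. The adjusted p-values were then far larger. They were 3.5e-09 for myelin, 3.5e-09 for disease-associated microglia and 5.52e-09 for complement and lysosome, at estimated correlations of 0.0734, 0.142 and 0.0837. Arfgap2 (ENSMUSG00000027255.15) was also among the largest falls, with 152 counts in naive and 1 in demyelination libraries, a ratio of 161 with a counting interval of 28.4 to 6380. It was at 0 in 2 naive libraries as well and is uncertain. Leaving out 1 library ended the calls of Adamtsl4 (demyelination 3 or naive 6, adjusted p up to 0.077), Ddit4 (demyelination 6, 0.0621), Tmem125 (demyelination 2, 4 or 6, naive 3, 5 or 7, up to 0.081) and Irf9 (demyelination 3, 6 or 7, naive 2, 3, 4, 6 or 7, up to 0.146). With library totals in place of TMM the call of Ddit4 ended too (adjusted p = 0.0591, range over 11 alternatives 0.00649 to 0.0591), and the calls were 192 upward and 59 downward. The downward count moved more than the upward one: it was 50 without demyelination 3 (122 upward), 128 without demyelination 1 (184), 140 with the replicate number as a block (202) and 190 with the mitochondrial share as a covariate (234).

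**Figure D1:**
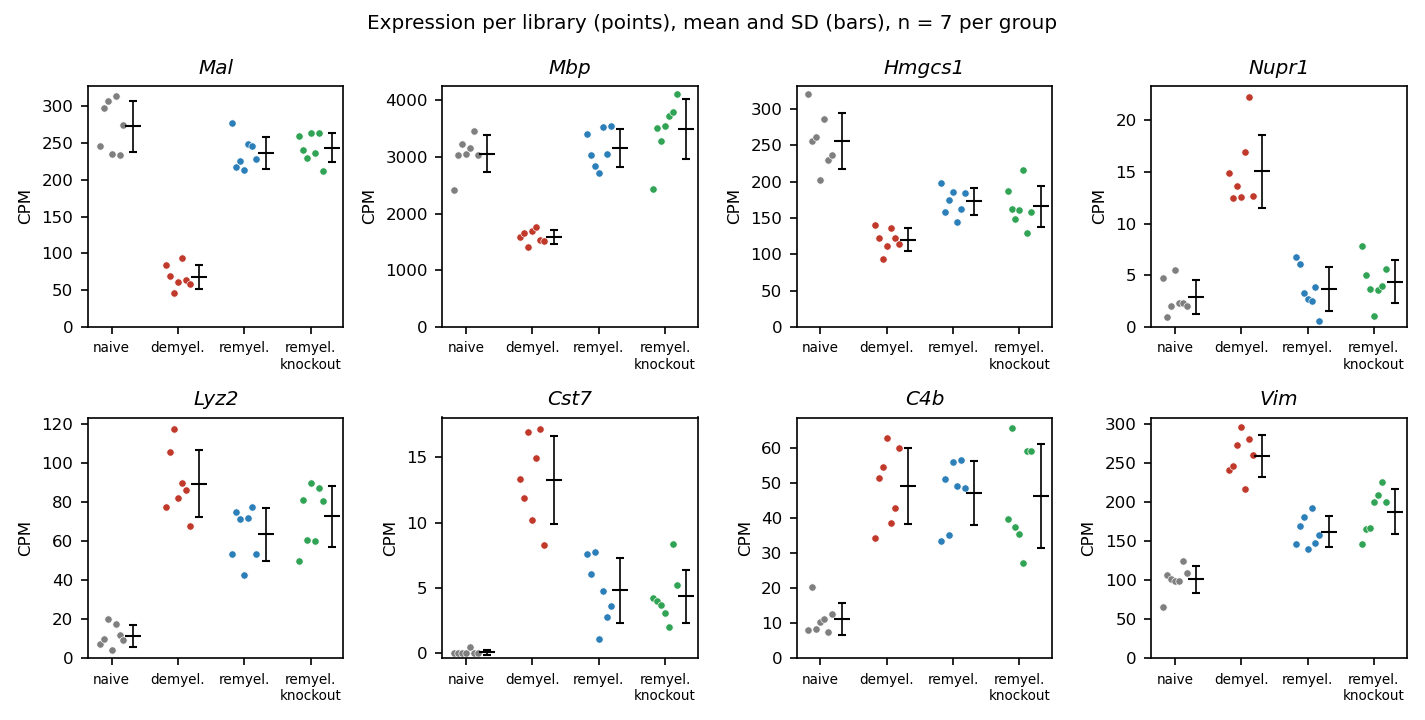
CPM per library (points) with mean and SD (bars) of Mal, Mbp, Hmgcs1, Nupr1, Lyz2, Cst7, C4b and Vim in the 4 groups of 7 libraries, each panel starting at 0 apart from that of Cst7, which starts slightly below it. Mal averaged 273, 68.0 and 237 CPM in naive, demyelination and remyelination libraries, while Lyz2 averaged 11.5, 89.4 and 63.4.

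In remyelination, microglial and astrocyte transcripts were still above naive brain, while immediate early genes lay below it. Lyz2 was 2.43 higher on the log2 scale (SE 0.203, 63.4 ± 13.5 against 11.5 ± 5.55 CPM, adjusted p = 8.36e-11) and C4b (ENSMUSG00000073418.5) 2.05 higher (SE 0.212, 47.2 ± 9.26 against 11.2 ± 4.48 CPM, adjusted p = 2.39e-08), with 7 libraries per group. Fos, an activity-induced transcription factor gene, was at 14.5 ± 4.65 CPM against 35.9 ± 7.98 and so fell by 1.28 (SE 0.227, adjusted p = 0.000664). In all, 78 genes differed from naive, 56 higher and 22 lower, and 35 by more than 2-fold.

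Of the 23 disease-associated microglia genes, 13 were raised (17 adjusted over the list alone, DESeq2 called 7, median +0.87, also with Clec7a at its bound, camera adjusted p = 6.64e-48). Lgals3 was at +3.14, Ccl6 at +2.94 and Cybb at +2.86. Clec7a had 74 counts against 0 and was at least 20.7-fold higher. Cst7 had 79 counts against 1, a ratio of 66.2 with a counting interval of 11.5 to 2650, and Itgax 109 against 3, a ratio of 30.5 with an interval of 10.2 to 150. Complement, Fc receptor and lysosome genes rose in 9 of 21 cases (14 adjusted over the list alone, camera adjusted p = 1.28e-27), with Ctss at +1.17 and Cd68 at +2.08. Homeostatic microglia genes rose in 3 of 16 (4 adjusted over the list alone, camera adjusted p = 4.36e-05). Among them were Fcrls at +1.02 and Csf1r at +0.62. The reactive astrocyte list had 4 of 15 raised (5 adjusted over the list alone, camera adjusted p = 3.44e-12). They were C4b, Serpina3n at +2.19, Gfap, the astrocyte filament, at +1.34 and Vim at +0.68 (named after its value was seen). Outside the lists Cd52 and Cd300c2 were 2.69 and 2.48 higher.

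The interferon list had 2 of 12 raised, Lgals3bp at +1.09 and Ifit3 at +1.11 (2 adjusted over the list alone, camera adjusted p = 0.00355). No antigen presentation gene of 7 passed over all genes (1 adjusted over the list alone, 3 at an unadjusted p under 0.05, DESeq2 called 0). The list as a whole was higher (median +0.35, camera adjusted p = 0.000232). Apoe was 0.80 higher and was the only 1 of 12 efflux and storage genes past the test (3 adjusted over the list alone, camera adjusted p = 0.000166). Of 24 cholesterol synthesis genes 2 were lower, Hmgcs1 at −0.57 and Sc5d at −0.52 (4 adjusted over the list alone, camera adjusted p = 0.000338). No myelin gene of 33 passed over all genes (4 lower adjusted over the list alone, 12 at an unadjusted p under 0.05, DESeq2 called 2). The list as a whole was lower, with a median of −0.20 (camera adjusted p = 3.22e-05). Among its members with the smallest p were Anln at −0.90 (adjusted p = 0.0597) and Gpr37 at −0.52 (0.106).

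The immediate early list had 3 of 13 members lower (5 adjusted over the list alone, median −0.22, camera adjusted p = 2.84e-07). They were Fos, the nuclear receptor Nr4a1 at −0.91 and the phosphatase Dusp1 at −0.73. Also lower were Sgk1, a glucocorticoid-induced kinase, at −0.99, Ddit4 at −0.89 and Tiparp at −0.94. So were Prlr at −0.77 and the integrin gene Itgb8 at −0.75. Hoxa5, at 0.480 ± 0.591 against 4.97 ± 4.58 CPM, had a log2 fold change of −3.37 (adjusted p = 0.0418). Nfkbia, the inhibitor of NF-kB, was 1 of 9 TNF and NF-kB targets to pass, at −0.70 (1 adjusted over the list alone, camera adjusted p = 0.433, median +0.02, mean −0.02, test downward). Ddit4 was the 1 stress response gene of 20 to pass (1 adjusted over the list alone, camera adjusted p = 0.485). Oxidative phosphorylation was higher as a list (median +0.12, camera adjusted p = 0.00721, but adjusted p = 0.292 with an estimated correlation) and none of 30 passed (3 at an unadjusted p under 0.05, DESeq2 called 0). None passed among newly formed oligodendrocyte (12 genes, 3 at an unadjusted p under 0.05, camera adjusted p = 0.401), precursor (15, 0, 0.83), cell cycle (7, 0, 0.888), M2 (3, 0, 0.894) and M1 genes (2 measured, 1). The M2 list had a median of +0.12 but a mean of −0.04. None of 22 neuron genes passed (2 at an unadjusted p under 0.05, camera adjusted p = 0.664, median +0.02, mean −0.01, test downward), though 1 fell adjusted over the list alone. DESeq2 called 1 neuron gene and 0 in the others of these lists.

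Among the lists for other cells, dissection, stress and RNA quality, red blood cell genes were higher (4 genes, median +0.64, camera adjusted p = 6.77e-06), with Hbb-bs past the test at +0.65 (4 adjusted over the list alone). Cerebellar genes were lower as a list (11 genes, median −0.27, camera adjusted p = 0.000135, and adjusted p = 0.0397 with an estimated correlation), with 0 past the test over all genes (6 adjusted over the list alone and at an unadjusted p under 0.05, DESeq2 called 2). The glucocorticoid list had 2 of 7 members higher and Sgk1 lower (3 and 1 adjusted over the list alone, median +0.18, camera adjusted p = 0.0246, but adjusted p = 0.192 with an estimated correlation). The 2 were Mt2 at +0.65 and Zbtb16, at 22.6 ± 4.17 against 9.60 ± 2.81 CPM (both named after their values were seen). The sex list was lower (4 genes, median −0.46, camera adjusted p = 0.00952, but adjusted p = 0.14 with an estimated correlation), with 0 past the test (1 adjusted over the list alone and at an unadjusted p under 0.05, DESeq2 called 1). Prlr was the 1 choroid plexus gene of 7 to pass (1 adjusted over the list alone, camera adjusted p = 0.0713). None passed among clock (12 genes, 3 at an unadjusted p under 0.05, camera adjusted p = 0.161), endothelial and mural (14, 4, 0.92, median −0.11, mean −0.02, test upward), meninges (8, 2, 0.46), mitochondrial (13, 1, 0.687), hypothalamus (4, 0, 0.224), olfactory bulb (5, 0, 0.348) and striatum genes (7, 0, 0.99, median +0.03, test downward). The same holds for the 2 lymphocyte, 2 ependymal and 1 monocyte genes (0 in each), and DESeq2 called 0 in these lists. Adjusted over the list alone, 1 clock gene was higher and 1 meninges and 1 mitochondrial gene lower.

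The other list calls of this comparison held with an estimated correlation, with myelin at an adjusted p = 0.0235. The count rose to 154 without remyelination library 1 and was 147 with DESeq2. The excess of higher over lower genes did not hold there, with 64 higher and 90 lower without that library and 74 and 73 with DESeq2, nor with the replicate number as a block (73 and 74) or the mitochondrial share as a covariate (82 and 81). Without the low-count filter 80 were higher and 42 lower. Anln passed without naive 4, remyelination 1 or remyelination 3 (lowest adjusted p = 0.03). Leaving out 1 library ended the calls of Cd300c2 (naive 1, 2, 4, 6 or 7, remyelination 4, 5, 6 or 7, adjusted p up to 0.0772), Hoxa5 (naive 2, 3, 5 or 6, remyelination 1, 2, 4, 5, 6 or 7, up to 0.127), Ifit3 (naive 1, 5, 6 or 7, remyelination 2, 3 or 4, up to 0.0876), Prlr (naive 1, 2 or 5, remyelination 2, 3, 4 or 5, up to 0.102) and Sc5d (naive 1 or 2, remyelination 3, 4 or 6, up to 0.0779). Over the other alternatives the highest adjusted p was 0.0877 for Hoxa5, 0.0645 for Ifit3, 0.0766 for Prlr and 0.0626 for Sc5d.

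**Figure D2:**
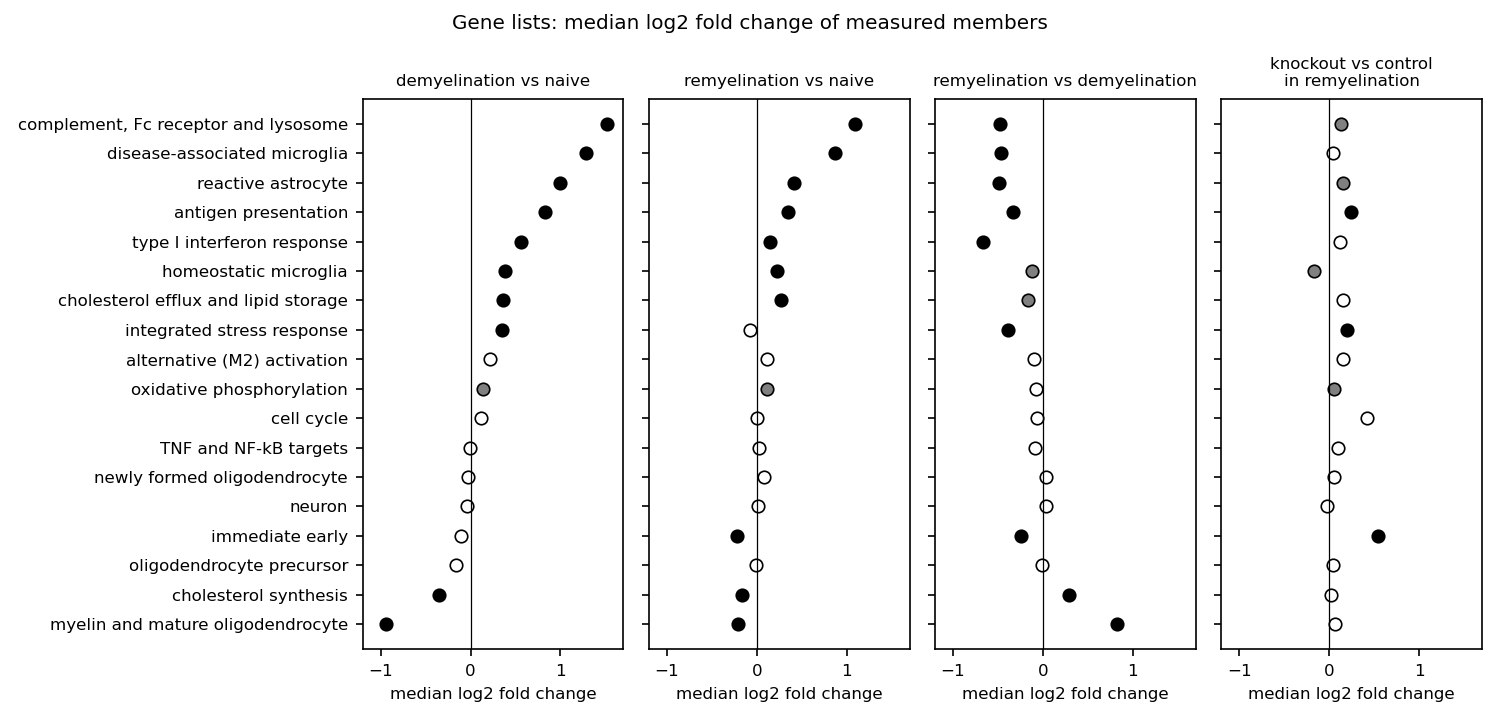
Median log2 fold change of 18 gene lists in the 4 comparisons, with black dots for lists called by camera with the preset and with an estimated correlation, grey dots for lists called with the preset alone and white dots for lists not called. The myelin list had medians of −0.94 in demyelination and −0.20 in remyelination against naive, and the disease-associated microglia list +1.29 and +0.87.

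Between the peak of demyelination and remyelination, myelin transcripts rose and those of activated microglia, astrocytes and stress responses fell. Mal rose by 1.80 on the log2 scale (SE 0.114, 68.0 ± 16.4 to 237 ± 22.2 CPM, adjusted p = 7.02e-15) and Mbp (myelin basic protein) by 0.99 (SE 0.096, 1592 ± 123 to 3159 ± 336 CPM, adjusted p = 4.56e-09), with n = 7 per group. Nupr1, a stress-induced chromatin protein gene, fell by 1.99 (SE 0.34, 15.1 ± 3.55 to 3.67 ± 2.14 CPM, adjusted p = 0.000582) and Ctsd by 0.64 (SE 0.12, 348 ± 73.3 to 223 ± 25.1 CPM, adjusted p = 0.00239). In this comparison 48 genes changed, 25 upward and 23 downward, 16 of them by more than 2-fold.

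Of 33 myelin genes, 13 rose (23 rose and 1 fell adjusted over the list alone, median +0.83, camera adjusted p = 2.24e-65). Among them were Ppp1r14a at +1.73, Opalin at +1.31, Mog at +1.16, Mag at +1.15 and Mobp at +1.02. Arfgap2, uncertain as above, had 330 counts against 1, a ratio of 292 with a counting interval of 52.1 to 11600. Hmgcs1 rose by 0.53 and was the 1 cholesterol synthesis gene of 24 to pass (3 adjusted over the list alone, median +0.29, camera adjusted p = 3.76e-08). No newly formed oligodendrocyte gene of 12 passed (0 at an unadjusted p under 0.05, DESeq2 called 0, camera adjusted p = 0.797, median +0.04 but mean −0.02), and none of 15 precursor genes (1 at an unadjusted p under 0.05, DESeq2 called 0, camera adjusted p = 0.894).

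Microglial, astrocyte and interferon lists fell. Of 23 disease-associated microglia genes 2 fell, Ctsd and Cst7 at −1.43 (13 adjusted over the list alone, DESeq2 called 4, median −0.47, camera adjusted p = 1.65e-19). Of 21 complement and lysosome genes 2 fell, Ctsl at −0.53 and Ctss at −0.52 (11 adjusted over the list alone, camera adjusted p = 3.38e-13). Vim at −0.67 was the 1 reactive astrocyte gene of 15 to fall (7 adjusted over the list alone, camera adjusted p = 1.14e-08). Lgals3bp, at −0.73, was the 1 interferon gene of 12 (4 adjusted over the list alone, camera adjusted p = 4.31e-08), and B2m, at −0.76, the 1 antigen presentation gene of 7 (2 and 0.000185). The stress response list had Nupr1 and Slc7a11, the cystine transporter, at −0.80 as the 2 of 20 that fell (8 adjusted over the list alone, camera adjusted p = 1.03e-10). Outside it the stress-linked transcription factor genes Atf5, Creb3l1 and Cebpd fell by 2.06, 1.34 and 1.05. The collagen gene Col5a3 fell by 2.71, from 13.3 ± 1.54 to 1.95 ± 1.2 CPM, and the macrophage gene Mpeg1 by 1.01. Fos fell by 1.07 and was the 1 immediate early gene of 13 to pass (5 adjusted over the list alone, DESeq2 called 3, median −0.24, camera adjusted p = 7.25e-07). Nfkbia was 1 of 9 TNF and NF-kB targets to pass, at −0.48 (1 adjusted over the list alone, camera adjusted p = 0.17).

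Among the lists for other cells, dissection, stress and RNA quality, red blood cell genes rose in 2 of 4 cases, Hba-a2 at +0.84 and Hba-a1 at +0.91, the latter named after its value was seen (4 adjusted over the list alone, median +0.67, camera adjusted p = 1.17e-07). The glucocorticoid list fell, with Sgk1 at −0.87 the 1 member of 7 past the test (3 adjusted over the list alone, median −0.32, camera adjusted p = 3.58e-05). Choroid plexus genes were lower as a list (7 genes, median −0.45, camera adjusted p = 0.00167, but adjusted p = 0.0578 with an estimated correlation), with Ttr, which encodes transthyretin, at −0.51 (adjusted p = 0.141). Striatal genes were higher as a list (7 genes, median +0.16, camera adjusted p = 0.0425, but adjusted p = 0.213 with an estimated correlation). In these 2 lists 0 genes passed (2 and 1 at an unadjusted p under 0.05, DESeq2 called 0), and 1 choroid plexus gene was lower adjusted over the list alone. None passed among cerebellum (11 genes, 1 at an unadjusted p under 0.05, camera adjusted p = 0.069), clock (12, 0, 0.687), endothelial and mural (14, 1, 0.814, median +0.03, mean −0.03, test upward), hypothalamus (4, 1, 0.488), meninges (8, 3, 0.702), olfactory bulb (5, 0, 0.547), sex (4, 0, 0.168) and mitochondrial genes (13, 0, 0.958, median +0.02, mean −0.01, test upward). The same holds for the 2 lymphocyte (1), 2 ependymal (0) and 1 monocyte genes (0), and DESeq2 called 0 in these lists. Adjusted over the list alone, 1 endothelial and 1 hypothalamus gene were higher.

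The homeostatic microglia list (median −0.12, camera adjusted p = 0.035, but adjusted p = 0.16 with an estimated correlation) and the efflux and storage list (median −0.16, 0.00326, but adjusted p = 0.0666 with an estimated correlation) had no member past the test over all genes. Adjusted over the list alone, 2 of 16 and 3 of 12 were lower (2 and 4 at an unadjusted p under 0.05, DESeq2 called 1 and 0). No neuron (22 genes, 2 at an unadjusted p under 0.05, camera adjusted p = 0.553), oxidative phosphorylation (30, 1, 0.265), cell cycle (7, 1, 0.597), M2 (3, 0, 0.654) or M1 gene (2 measured, 0) passed, and DESeq2 called 0 of them. All other list calls held with an estimated correlation. The downward count was 14 without demyelination 4, 13 without remyelination 4, 39 without the low-count filter and 38 with DESeq2, beside 20, 22, 33 and 33 upward. Leaving out 1 library ended the calls of Cst7 (demyelination 3, 5 or 6, remyelination 4, 6 or 7, adjusted p up to 0.0733), Ctsl (demyelination 4 or 6, remyelination 4, up to 0.0799), Ctss (demyelination 2, 3, 4 or 5, remyelination 3, 4 or 6, up to 0.106), Lgals3bp (demyelination 3, 4, 6 or 7, remyelination 1, 2, 3, 4 or 6, up to 0.141), Creb3l1 (demyelination 4, 6 or 7, remyelination 1, 3, 4, 6 or 7, up to 0.091), Cebpd (demyelination 4 or remyelination 4, up to 0.091) and Fos (demyelination 4, 0.0681). Over the other alternatives the highest adjusted p was 0.0718 for Creb3l1 and 0.0587 for Opalin. Calls absent from the main test were gained with DESeq2 and other settings for Tyrobp, Dusp1, Nr4a1 and Psph. Their adjusted p over 11 alternatives ranged from 0.00651 to 0.0538, 0.0114 to 0.126, 0.0173 to 0.0934 and 0.0268 to 0.139.

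The return toward naive brain was counted for genes raised and lowered at the peak of demyelination, and the difference between the 2 directions was not tested. Of the 249 genes changed at the peak of demyelination, 57 were still changed in the same direction in remyelination against naive (22.9%, exact 95% interval 17.8 to 28.6%). They were 51 of the 162 raised genes (31.5%) and 6 of the 87 lowered genes (6.9%), where the count of 87 moved with the settings as given above. In the opposite direction 34 were called between demyelination and remyelination (13.7%, 9.65 to 18.6%). They were 14 of the raised (8.64%) and 20 of the lowered genes (23%). Independent lists of these sizes would share 0.73 raised and 0.154 lowered genes in the first overlap and 0.3 and 0.175 in the second. These comparisons share libraries. With the naive libraries divided between them the first share was 13.7 and 18.8%, and with the demyelination libraries divided the second was 8.61 and 7.31%. Across all genes the covariance of the log2 fold changes was 0.0728 for demyelination and remyelination against naive (r = 0.672), with 0.0257 in 10 simulations of unchanged groups (r = 0.508). It was −0.0517 for the second pair (r = −0.542), with −0.0256 in simulation (r = −0.506). The simulations drew genes independently and held no library that stood apart, so their covariances may be too near 0. With the libraries divided as above, so that none was shared, the covariance was 0.0437 and 0.0387 for the first pair. For the second pair it was −0.032 and −0.0211. A gene no longer called had not necessarily returned to its naive level. The ratio of the log2 fold change in remyelination to that in demyelination, both against naive, measures the size kept. Its median was 0.627 for the raised and 0.394 for the lowered genes. Genes are not independent replicates, although the exact intervals above treat them so.

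In remyelination, the knockout group had higher immediate early transcripts and lower Cx3cr1 than the control group, with little else past the test. The labels name the recombinase in the Cx3cr1 locus and tamoxifen for the knockout group only, and do not say whether controls received tamoxifen. Its differences from control therefore do not separate the TNFR1 deletion from that allele or from tamoxifen. Fos (ENSMUSG00000021250.14) rose by 1.23 on the log2 scale (SE 0.226, 34.7 ± 9.52 against 14.5 ± 4.65 CPM, n = 7 per group, adjusted p = 0.00855) and each of the 7 knockout libraries lay above every control library. Nr4a1 rose by 0.96 (SE 0.154, 78.7 ± 10.8 against 40.1 ± 8.14, adjusted p = 0.00268). Arc, which encodes a synaptic capsid-like protein, rose by 0.93 (SE 0.158, 80.0 ± 15 against 41.8 ± 10.1, adjusted p = 0.0041) and Dusp1 by 0.89 (SE 0.162, adjusted p = 0.00855). Cx3cr1 (ENSMUSG00000052336.8), the fractalkine receptor of microglia, whose locus carries the recombinase in this line, fell by 0.89 (SE 0.183, 26.1 ± 11.8 against 48.9 ± 7.8 CPM, adjusted p = 0.0365). With Ddit4, an inhibitor of mTORC1, at +0.71 (adjusted p = 0.026), 6 genes changed in all, 5 upward and 1 downward. At an unadjusted p under 0.05 there were 930, where chance gives 621 on average. The same count was 1649, 1294 and 826 in the comparisons of demyelination with naive, remyelination with naive and remyelination with demyelination. Genes vary together, so such counts can lie far from 621 by chance, and the excess was not tested.

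The immediate early list was higher as a whole: 4 of 13 members rose (7 adjusted over the list alone), 12 lay above 0, and the median was +0.55 (camera adjusted p = 5.56e-15, 0.000166 with an estimated correlation). The integrated stress response list had 1 of 20 raised, Ddit4 (2 adjusted over the list alone, median +0.20, camera adjusted p = 0.00054), with Psat1, a serine synthesis enzyme, at +0.46 (adjusted p = 0.287). The antigen presentation list was higher as a list (median +0.25, camera adjusted p = 0.00721) with none of 7 passing over all genes (2 adjusted over the list alone and at an unadjusted p under 0.05, DESeq2 called 1). Its B2m was at +0.45 (adjusted p = 0.13, 0.0373 without knockout 5) and H2-D1 at +0.45 (0.535).

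The myelin list had no call here. Of 33 genes 0 passed (1 at an unadjusted p under 0.05, DESeq2 called 0), with a median of +0.06 (camera adjusted p = 0.0544). Efhd1, Qdpr and Mog, its members with the smallest p, were at +0.33, +0.18 and +0.24 (adjusted p = 0.628, 0.669 and 0.674). Of 23 disease-associated microglia genes 0 passed (3 at an unadjusted p under 0.05, DESeq2 called 0, camera adjusted p = 0.888, median +0.05, mean −0.04). Lgals3 was at −0.68 and Cybb at −0.85 (adjusted p = 0.646 and 0.57). Cx3cr1 was the 1 homeostatic microglia gene of 16 to fall (1 adjusted over the list alone, median −0.17, camera adjusted p = 0.044, but adjusted p = 0.177 with an estimated correlation). P2ry12 and Sall1 were at −0.48 and −0.60 (adjusted p = 0.623 and 0.635). The complement and lysosome list (21 genes) had a median of +0.13 (camera adjusted p = 0.0452, but adjusted p = 0.224 with an estimated correlation). The reactive astrocyte list (15 genes) had a median of +0.15 (camera adjusted p = 0.014, but adjusted p = 0.0803 with an estimated correlation), and oxidative phosphorylation (30 genes) of +0.06 (camera adjusted p = 0.018, but adjusted p = 0.347 with an estimated correlation). No member of these 3 lists passed over all genes (3, 1 and 4 at an unadjusted p under 0.05, DESeq2 called 0). Adjusted over the list alone, 1 oxidative phosphorylation gene passed.

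No TNF and NF-kB target of 9 passed over all genes (2 at an unadjusted p under 0.05, DESeq2 called 1, camera adjusted p = 0.255), while Nfkbia, at +0.47 (adjusted p = 0.163), passed adjusted over the list alone. None passed among interferon (12 genes, 2 at an unadjusted p under 0.05, camera adjusted p = 0.0653), cholesterol synthesis (24, 2, 0.0755), efflux and storage (12, 1, 0.0917) and precursor genes (15, 1, 0.721, median +0.05 but mean −0.05). None passed among newly formed oligodendrocyte (12, 0, 0.654), neuron (22, 4, 0.683), cell cycle (7, 2, 0.292), M2 (3, 0, 0.956, median +0.15, mean +0.08, test downward) and M1 genes (2 measured, 0) either. DESeq2 called 0 members of these lists.

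Among the lists for other cells, dissection, stress and RNA quality, choroid plexus genes were higher as a list (7 genes, median +0.45, camera adjusted p = 0.00102, and adjusted p = 0.0479 with an estimated correlation), with Ttr at +0.64 (adjusted p = 0.114). So were red blood cell genes (4 genes, median +0.52, camera adjusted p = 0.00102, but adjusted p = 0.101 with an estimated correlation) and cerebellar genes (11 genes, median +0.15, camera adjusted p = 0.00102, but adjusted p = 0.0671 with an estimated correlation). Meninges genes were higher too (8 genes, median +0.36, camera adjusted p = 0.0111, but adjusted p = 0.126 with an estimated correlation). No member of these 4 lists passed over all genes (3, 3, 4 and 2 at an unadjusted p under 0.05, DESeq2 called 0), while 3, 3, 3 and 0 rose adjusted over the list alone. None passed among clock (12 genes, 1 at an unadjusted p under 0.05, camera adjusted p = 0.814, median −0.02, mean +0.04, test upward), endothelial and mural (14, 0, 0.646), glucocorticoid (7, 1, 0.799), hypothalamus (4, 0, 0.484), mitochondrial (13, 0, 0.136), olfactory bulb (5, 0, 0.958, median +0.12, mean +0.04, test downward), sex (4, 0, 0.814) and striatum genes (7, 0, 0.916). The same holds for the 2 lymphocyte, 2 ependymal and 1 monocyte genes (0 in each), and DESeq2 called 0 in these lists. Per1, a clock gene that also responds to activity, was at +0.54 (adjusted p = 0.535) and rose adjusted over the list alone.

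The Cx3cr1 call ended without any 1 of 9 libraries (knockout 2, 3, 4 or 6, remyelination 1, 2, 3, 5 or 6, adjusted p 0.0628 to 0.174), with only the 2 groups compared (0.323), with library totals (0.084) and with the replicate number as a block (0.0569), in a range over 11 alternatives of 0.000673 to 0.323. That of Ddit4 ended without any 1 of 7 (knockout 1, 2 or 4, remyelination 1, 2, 3 or 6, 0.0612 to 0.0924), with only the 2 groups compared (0.0679), with library totals (0.084) and without naive 1 and knockout 1 together (0.0678), in a range of 0.00288 to 0.084. Fos, Nr4a1, Arc and Dusp1 kept their calls without each library. No gene passed a test for a minimum fold change (glmTreat), and DESeq2 called 11 genes.

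**Figure D3:**
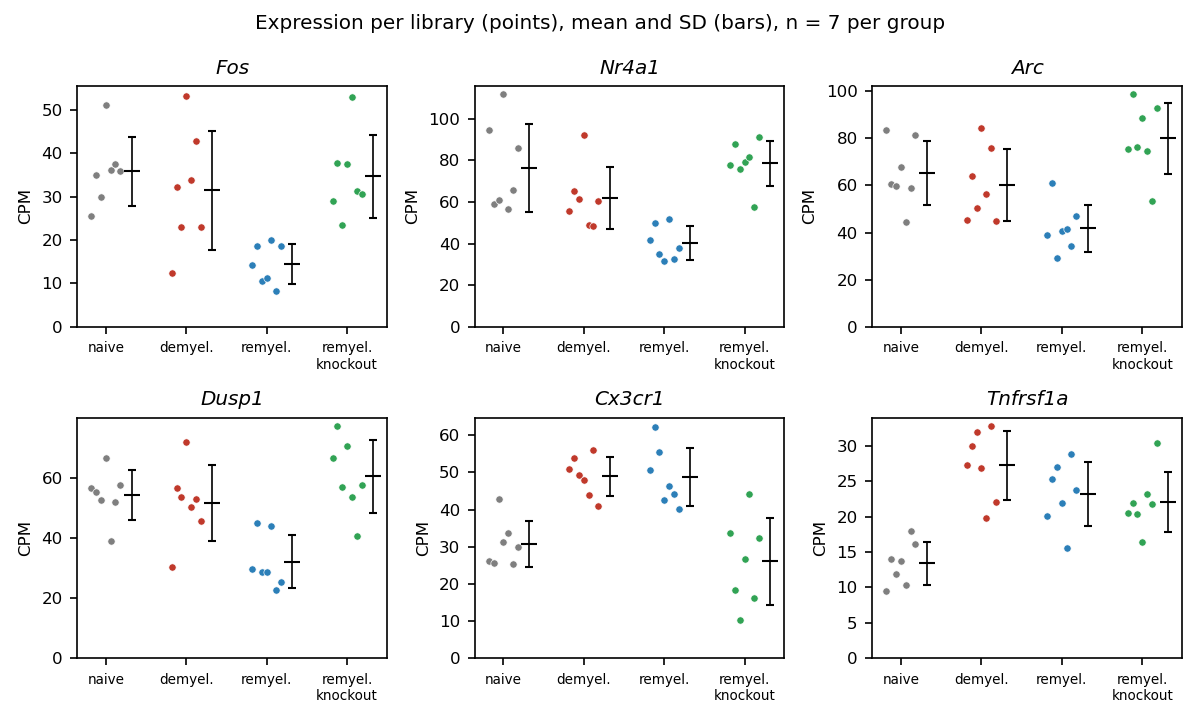
CPM per library (points) with mean and SD (bars) of Fos, Nr4a1, Arc, Dusp1, Cx3cr1 and Tnfrsf1a in the 4 groups of 7 libraries, each panel starting at 0. Fos averaged 35.9 CPM in naive, 31.5 in demyelination, 14.5 in remyelination control and 34.7 in knockout libraries, and Cx3cr1 30.7, 49.0, 48.9 and 26.1.

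The demyelination score, built from 136 genes raised and 85 lowered between naive and demyelination libraries, asked whether knockout brains lay nearer to either state. It was −0.49 ± 0.159 in knockout and −0.54 ± 0.150 in control remyelination libraries (n = 7 per group), a difference of +0.06 (two-sided exact permutation p = 0.519 over 3432 splits). The naive and demyelination groups, from which the genes were chosen, scored −1.59 ± 0.082 and 0.49 ± 0.237. Leaving out single libraries moved the difference between −0.05 and 0.12, so its sign was not determined.

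**Figure D4:**
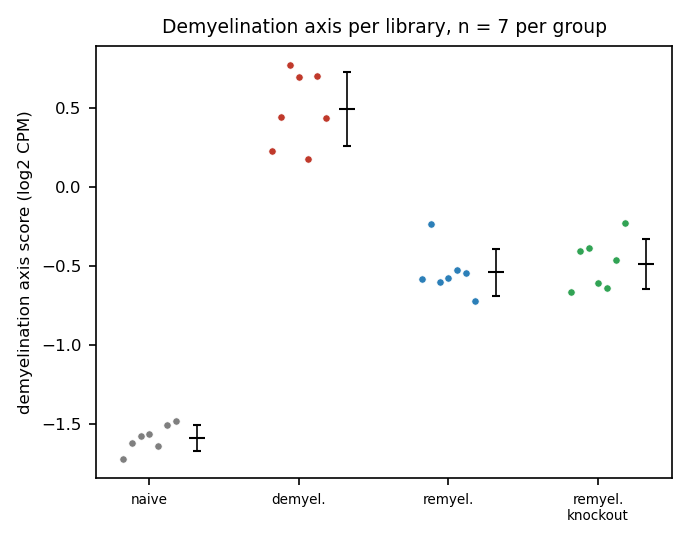
Demyelination score per library (points, in log2 CPM) with mean and SD (bars) for the 4 groups of 7 libraries. The separation of the naive and demyelination groups follows from how the genes were chosen. Knockout libraries averaged −0.49 and control remyelination libraries −0.54, both between the other groups.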

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

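The test of low immediate early transcripts in the control group, that of the Cx3cr1 allele and the splits of knockout against naive libraries were chosen after the results they concern had been seen.

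Immediate early genes were higher in knockout than in control remyelination brains, with a list median of +0.545. Without knockout library 1 the median was 0.532 and with the mitochondrial share as a covariate 0.527, so neither that library nor the share accounts for it. Time of day at collection stays open, because the clock list gave a camera adjusted p of 0.814 while its activity-responsive member Per1 rose adjusted over the list alone. Against naive brain the knockout median was 0.135, and against demyelination 0.232, so a low level in the control remyelination libraries is a candidate explanation for the difference. Dissection and tissue composition were not tested. In the same comparison choroid plexus genes were higher as a list (camera adjusted p = 0.00102, 0.0479 with an estimated correlation). So were cerebellar, red blood cell and meninges genes, though those calls did not hold with an estimated correlation. The striatum, hypothalamus and olfactory bulb lists were not called. A response to the loss of TNFR1 in microglia, which the design names, was not tested apart from these explanations, from the recombinase in the Cx3cr1 locus or from tamoxifen, which the labels name for the knockout group only.

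Cx3cr1 was lower in knockout than in control remyelination brains. The other 15 homeostatic microglia genes measured had a median of −0.087 (bootstrap SE over genes 0.173). Fewer microglia alone would lower them about as far as Cx3cr1. Their median lay above the mark set beforehand, −0.446 or the Cx3cr1 fold change divided by 2, by little more than 2 SE. That SE treats genes as replicates, so a partial loss of microglia stays open. The fold change of −0.892 has a 95% interval of −1.263 to −0.522 that includes −1, the loss of 1 of 2 alleles. Replacement of 1 Cx3cr1 allele by the recombinase may therefore account for the mean difference if the controls lacked it. It does not by itself predict the spread between libraries. Knockout libraries ranged from 10.4 to 44.3 CPM (SD 11.8) and control libraries from 40.3 to 62.2 CPM (SD 7.8). The cause of that spread was not tested. The labels name the recombinase and tamoxifen for the knockout group only and do not say that the controls had neither, so an effect of the TNFR1 deletion on Cx3cr1 was not separated from that of the allele or of tamoxifen.

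Naive library 1 and knockout library 1 stood apart from their groups. In naive library 1 the most abundant gene took 25.54% of counts (nearest other 10.16%), 15862 genes were detected (17630) and Mbp was at 2424 CPM (3039). In knockout library 1 mitochondrial transcripts made up 9.143% (5.977%) and Clec7a was at 18.72 CPM (5.589). A swap of the 2 is argued against by Lyz2, at 49.5 CPM in knockout library 1, where the highest of the other naive libraries had 20.1. Thinned to the same number of counts outside the most abundant gene, the 2 held 15861 and 15811 genes where every other library held at least 16488, so lower complexity of the library is a candidate explanation, and no biological one was tested.

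Other libraries far from the rest of their group were these, with the nearest other library in brackets. The demyelination score of remyelination library 2 was −0.233 (−0.527). Cst7 was at 0.4697 CPM in naive library 5 (0), which is 1 count and below the floor of 3. Itgax was at 21.55 CPM in demyelination library 4 (14.15) and at 1.591 CPM in naive library 1 (0.485), and C4b at 20.37 CPM in naive library 2 (12.64). Nr4a1 was at 92.21 CPM in demyelination library 4 (65.15), Ddit4 at 32.44 CPM in remyelination library 5 (26.34) and Ttr at 725.8 CPM in knockout library 3 (1002). Arfgap2 was at 0.4823 CPM in demyelination library 5 (0), also 1 count, and Hoxa5 at 1.651 CPM in remyelination library 3 (0.6361). For normally distributed values chance alone gives such a library in about 1 of 20 groups tested, and here 15 of 123 had one. Values near the floor are not so distributed.

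Each comparison was repeated on 100 splits of its 14 libraries, the real one included, in fits of only the 2 groups. In each of the 5 comparisons only 1 of the 100 splits, the real one, gave as many called genes. These are a sample of the possible splits, so chance became unlikely as the source of the counts but was not excluded. The splits say nothing of other differences between the groups. The real split and the highest other gave 286 and 2 genes for demyelination against naive, 82 and 69 for remyelination against naive, 47 and 10 for remyelination against demyelination, 4 and 1 for knockout against control, and 360 and 35 for knockout against naive.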

How the results depend on the processing

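The robust spread, the omission of naive 1 and knockout 1 and the comparisons of the knockout group with naive and demyelination brains were chosen after the data were seen. The targeted gene is given below. Of 3754 values of the other 140 named-gene results, 3530 kept their direction and side of the threshold, 177 lost their call, 47 gained one and 0 reversed. Where no cause is given, it was not tested. A stricter adjusted p of 0.01 left 142, 45 and 28 genes for demyelination against naive, remyelination against naive and remyelination against demyelination, and a minimum fold (glmTreat) left 115, 38, 20 and, for knockout against control, 0, both by construction. Without the low-count filter 122 (remyelination against naive) and 28 (knockout against control) were called, with the mitochondrial covariate 424 (demyelination against naive) and 163 (remyelination against naive), and with DESeq2 147 (remyelination against naive) and 11 (knockout against control). With the replicate number as a block 342, 147, 53 and 6 were called. Only 5 of 42 pairs of libraries with the same number correlated above 0.1 (r from −0.1315 to 0.3019). Yet 10 of the 28 libraries correlated best with a library of their own number in another group. Whether the numbers pair the samples was not settled, and the main test used no pairing. With library totals the median of all genes lay at most 0.039 (log2) from 0. Each library left out in turn gave 172 to 312, 57 to 154, 34 to 56 and 4 to 8 genes, with 154 without remyelination 1. Without naive 1 and knockout 1 there were 280, 71, 64 and 5, and with the robust spread 254, 76, 49 and 6.

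The targeted gene ranged from −0.148 (without knockout 7) to 0.014 over single libraries left out, and turned to 0.014 without knockout 4 and 0.011 without remyelination 6. The difference in demyelination score ranged from −0.046 to 0.121 over single libraries left out, and was negative without demyelination 3 (−0.046), 4 (−0.033), 6 (−0.012) or 7 (−0.008) and without naive 2 (−0.045), 3 (−0.004), 4 (−0.008), 5 (−0.007) or 7 (−0.003). Of the lists in knockout against control, the disease-associated microglia median was 0.017 with the test downward without naive 1 and knockout 1. With divided libraries the shares of the demyelination response kept or opposed were 13.7 and 18.8% (kept) and 8.61 and 7.31% (opposed). This removes shared libraries and also leaves fewer per test, and the 2 were not separated. A sex term was not run. Depth limits the tests of Tnf, Tnfrsf1b and other genes near the floor of 3 counts.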

Other observations

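The comparison of knockout with naive brains, its lists and its genes, and the counts at an unadjusted p and by DESeq2, were chosen after the data were seen, so the genes named here are named after their values were seen. Its camera p-values were adjusted over the lists of each kind in this comparison alone, unlike those of the 4 planned comparisons. Knockout remyelination brains were above naive in microglial, astrocyte and antigen presentation genes. Lyz2 was 2.63 higher on the log2 scale (SE 0.203, 72.6 ± 15.7 against 11.5 ± 5.55 CPM, n = 7 per group, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.63e-12) and C4b 2.03 higher (SE 0.212, adjusted p = 2.68e-08). Of 23 disease-associated microglia genes 16 were raised (18 adjusted over the list alone, camera adjusted p = 7.86e-35), of 21 complement and lysosome genes 11 (18, 7.58e-27) and of 15 reactive astrocyte genes 6 (8, 9.03e-15), with Gfap at +1.59 and Vim at +0.89. Antigen presentation had 3 of 7 raised (3 adjusted over the list alone, 3.83e-07), among them B2m at +0.78, interferon genes 4 of 12 (4, 0.000103) and efflux and storage genes 3 of 12 (5, 8.67e-06), with Apoe at +0.98. All 4 red blood cell genes measured were higher (camera adjusted p = 5.46e-11, 0.00163 with an estimated correlation). Glucocorticoid response genes were higher as a list (camera adjusted p = 0.031, but adjusted p = 0.209 with an estimated correlation), with Mt2 and Mt1 at +0.68 and +0.56 and Sgk1 lower at −0.685. Sex-linked genes were lower as a list (camera adjusted p = 0.0243, but adjusted p = 0.209 with an estimated correlation), with Eif2s3y at −0.98. Of 7 choroid plexus genes Ttr was higher at +0.56 and Prlr lower at −0.685 (camera adjusted p = 0.514). The clock gene Dbp was at +0.68 (0.168) and the endothelial and mural list had Vtn at +0.52 (0.514).

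Neuron genes went both ways against naive, and the oligodendrocyte genes past the test were lower. Of 33 myelin genes 3 were lower, Anln at −1.10, Ermn at −0.75 and Gpr37 at −0.51 (camera adjusted p = 0.0754), and of the precursor genes Pcdh15 was lower at −0.81. Of 22 neuron genes 3 were lower, the glutamate and GABA genes Slc17a6, Gria2 and Gad2 at −0.44, −0.41 and −0.38, and Thy1 was higher at +0.40 (0.475). The cholesterol synthesis genes Idi1, Hmgcs1 and Sc5d were at −1.27, −0.62 and −0.56 (3 of 24 lower, 0.132). Of 16 homeostatic microglia genes 3 were higher, among them Fcrls and Csf1r at +1.28 and +0.53, and 1 was lower, P2ry12, a purine receptor, at −0.71 (0.0943). Oxidative phosphorylation was higher as a list (median +0.19, camera adjusted p = 4.08e-05, but adjusted p = 0.127 with an estimated correlation), with 1 of 30 past the test, Cox5b at +0.32 (12 adjusted over the list alone). Immediate early, stress response and TNF target genes had 0 members past the test (0, 4 and 1 at an unadjusted p under 0.05, DESeq2 called 0).

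In all 403 genes differed between knockout and naive brains, 191 higher and 212 lower. The larger share was upward at an adjusted p under 0.01 (73 higher and 46 lower), with glmTreat (44 and 6), with library totals (138 and 105), with DESeq2 size factors (198 and 182), with at least 1 CPM in 7 libraries (151 and 140), with the mitochondrial covariate (152 and 142) and without any single knockout or naive library other than knockout 1 and naive 6 (for example 87 and 59 without knockout 7), while DESeq2 gave 279 each way, so the balance of directions was not determined. The count was 558 with DESeq2, 119 at an adjusted p under 0.01, 50 with glmTreat, 608 with the replicate number as a block, 644 without naive 1 and knockout 1, and 243 with library totals. Leaving out single libraries gave 146 to 736, with 146 without knockout 7, 736 without knockout 1, 233 without knockout 3, 219 without knockout 6, 205 without naive 2, 257 without naive 3 and 196 without naive 5. Against demyelination 75 genes differed, with Cx3cr1 at −0.89 (adjusted p = 0.00759), while against naive it was at −0.22 (adjusted p = 0.561). That more genes differed from naive in the knockout than in the control group was not tested.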
